A study of Mus musculus with 30 samples.

How the data were processed

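The series holds 30 arrays of total RNA from a mouse embryonic stem cell clone, called NgR in the labels, in which Nanog depends on doxycycline. Per the labels, the clone was derived from rtTA-expressing Ainv15 cells, was kept on primary mouse embryonic fibroblasts, and was grown with doxycycline at 1 ug/ml before withdrawal. The 10 groups held 3 arrays each. They were day 0 with doxycycline, days 1, 3 and 5 after withdrawal, and, for each of these 3 days, a further 12 h either with a doxycycline pulse or without it as the time-matched control.

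RNA was hybridized to Affymetrix Mouse Gene 1.0 ST arrays. The deposited values are log2 signal intensities per transcript cluster, a set of probes for 1 transcription unit, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, equalizes the distributions of the arrays and summarizes the probes of a cluster. The notes give neither software versions nor an annotation release or genome build, so no coordinates are printed. Arrays have no read depth, and precision here is limited by 3 arrays per group and by differences in spread between arrays. The 28815 clusters were named through the platform table of the deposit. Of these, 21780 had 1 gene symbol, 1605 had several and 5430 had none. The 23385 clusters with a symbol were tested. Of these, 238 repeated the values of a tested cluster listed before them, and the reason was not examined. None of the 30 pairs of replicates held identical values.

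All 30 arrays were fitted together in limma 3.58.1 under R 4.3.3, with 1 mean per group and no covariate, since the labels give no array date or batch. Contrasts were tested with the moderated statistics of limma, and p-values were adjusted by the Benjamini-Hochberg method over the 23385 clusters within each contrast. A cluster was called at an adjusted p under 0.05. The contrasts were each withdrawal day against day 0, the steps from day 1 to day 3 and from day 3 to day 5, the pulse against its time-matched control on each day, the average of the 3 pulses, the differences between pulse effects, and the time-matched control against the same day's withdrawal group. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these arrays.

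A reversal slope was computed for each day, across the clusters called in that day's withdrawal, as the slope through 0 of the pulse change on minus the withdrawal change. It is 1 where the pulse effect equalled the withdrawal change in reverse on average, and 0 where there was none of it. The control went on changing over the 12 h, so the slope also counts change that the pulse prevented rather than undid. Withdrawal and pulse contrasts share no arrays. Two-sided exact permutation tests used the 20 assignments of the 6 arrays of a day, which can give no p below 0.1, and the 8000 combined assignments for the mean of the 3 slopes.

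Gene lists for 20 pathways and cell types were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists within a contrast. Each list was also counted member by member, adjusted over all clusters and adjusted over the list alone. The naive list includes Nanog itself, whose change with doxycycline was set by the clone, and no list test without Nanog was run. A gene with several clusters was given by the cluster with the highest mean over all arrays. The camera test was repeated with an estimated correlation, and fry was run as a further test. The test and the sample groups, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

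The named genes were fixed by rule. They are Nanog in each array, and, for each withdrawal, step and pulse contrast, the 8 called genes with the largest rise and the 8 with the largest fall among those with 1 symbol and no overlap between the arrays compared. For the pulse average this separation had to hold in the same direction within at least 2 of the 3 days. The rule also takes up to 4 called members of each list with the largest change, the 5 largest called differences between pulses, members given as not called, and a core set of Esrrb, Klf4, Klf2, Tbx3, Prdm14, Zfp42, Dppa3, Pou5f1, Sox2, Otx2, Fgf5, Gata6 and T in each contrast. No cluster matched T, so it was not analysed here. Clusters of microRNAs, small nucleolar RNAs and the Usp17l family share probes or near-identical copies, and their values are uncertain.

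The alternatives were moderated variances with trend and robust settings, array weights, a fit of the compared groups alone, median centring of each array, quantile normalization over the tested clusters, clusters in the lowest 40 percent of mean signal left out, clusters without a symbol included, a 2-fold minimum, the replicate number as a block, and each array left out in turn. After the data were seen, the interquartile range of each array was added as a covariate, and the 4 arrays with the widest range were left out, which leaves 1 control array on day 5, so that values of that fit for day 5 rest on a single control. The fit was tested on simulated data with the means of the day 0 arrays and the residual spread of each cluster, drawn independently, so without the shared array spread of the real data. In a simulated pulse of day 1 with 200 of 23385 clusters changed, 71 percent of changes of 0.5 and 100 percent of changes of 1 on the log2 scale were called in the right direction, with 8 false calls. A simulated reversal slope of 0.4 was recovered as 0.387, and in a simulated list test of the day 1 pulse the shifted list alone was called.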

Results

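Gene expression was measured on 30 arrays from the doxycycline-dependent Nanog clone NgR, 3 arrays in each of 10 groups. The comparisons address what changed over up to 5 days of withdrawal. They also ask how far a 12 h return of doxycycline moved those changes back, against the time-matched control. No arrays came from cells kept on doxycycline over these days, so withdrawal cannot be told apart from time in culture. No arrays came from cells in which Nanog did not depend on doxycycline, so an effect of doxycycline itself cannot be told apart from one of Nanog. The median signal of an array was 7.36 (log2) in replicate 1 of day 0, and its values ran from 2.31 to 14.1. Changes are log2 differences of group means with their standard errors, from 3 arrays against 3, and adjusted p-values are those of limma.

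Nanog itself followed doxycycline in each array. Its signal (cluster 10541524) was 11.03 ± 0.023 (SD, n = 3) at day 0 with doxycycline, and it fell to 10.24 ± 0.075 at day 1, 10.51 ± 0.050 at day 3 and 9.85 ± 0.21 at day 5 of withdrawal. The 3 pulsed groups returned to 11.09 ± 0.029, 10.97 ± 0.069 and 10.84 ± 0.15, against 10.30 ± 0.049, 10.17 ± 0.048 and 10.07 ± 0.026 in their time-matched controls. All 12 arrays with doxycycline lay at 10.70 or above and all 18 arrays without it at 10.57 or below. The pulse raised Nanog by 0.79 ± 0.080 on day 1, 0.80 ± 0.080 on day 3 and 0.78 ± 0.080 on day 5, with adjusted p = 3.33e-06, 4.61e-06 and 4.26e-06. Within the withdrawal, Nanog rose by 0.27 ± 0.080 from day 1 to day 3 (adjusted p = 0.0135) and fell by 0.66 ± 0.080 from day 3 to day 5 (adjusted p = 1.81e-06).

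**Figure D1:**
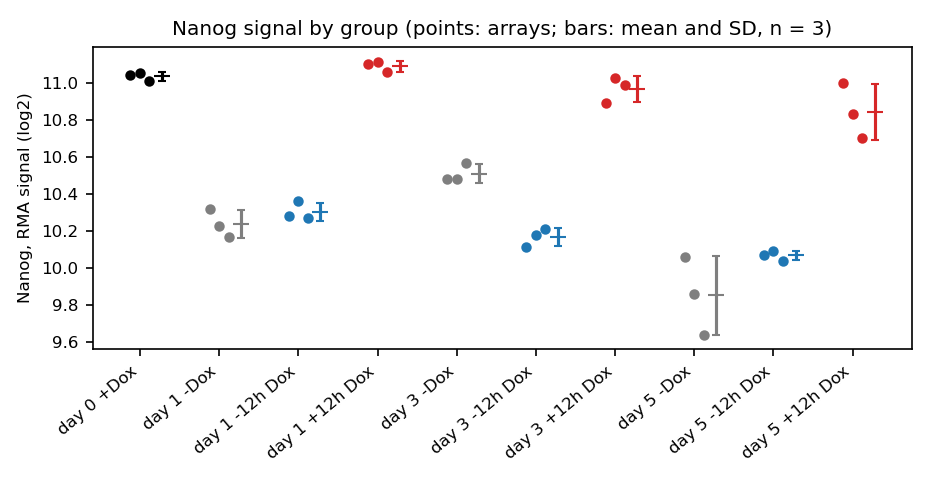
Nanog signal (RMA, log2) on the vertical axis for the 10 groups on the horizontal axis. Points are arrays and bars are group means with SD (n = 3). The 12 arrays with doxycycline lie at 10.70 or above, the 18 without it at 10.57 or below.

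At day 1 of withdrawal, genes of naive pluripotency were lower and genes of the formative epiblast, the state that embryonic stem cells enter as they leave naive pluripotency, were higher than at day 0. Otx2, a homeobox factor of that state, rose by 1.59 ± 0.11 (adjusted p = 2.38e-10), from 8.17 to 9.76. The iron exporter Slc40a1 rose by 1.30 ± 0.083, the cadherin Cdh9 by 1.19 ± 0.14, the receptor Lpar4 by 1.18 ± 0.12, the GTPase Irgm1 by 1.16 ± 0.15, and Lefty1, an antagonist of Nodal signalling, by 1.10 ± 0.13. Mras, a Ras-like GTPase in the naive list, fell by 1.94 ± 0.074 (adjusted p = 6.46e-16), followed by Serpinb6c (−1.33 ± 0.12), the KDEL receptor Kdelr3 (−1.14 ± 0.11), Rab27a (−1.10 ± 0.10) and Eras (−1.09 ± 0.12). The microRNA clusters Mir377 and Mir363 were also among the 8 largest rises, and Tmsb4x and 2210409E12Rik among the 8 largest falls.

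Of the 27 measured naive pluripotency genes, 12 fell at day 1, and 15 fell and 1 rose adjusted over the list alone. Besides Mras and Nanog (−0.80 ± 0.080), they included Calcoco2 (−1.08 ± 0.17) and the germline and naive factor Prdm14 (−0.75 ± 0.074). Klf4, Tbx3, Zfp42 and Esrrb fell by 0.51, 0.52, 0.38 and 0.36. The list was lower as a whole (camera adjusted p = 1.38e-12), with adjusted p = 0.0535 with an estimated correlation. Of 19 formative and primed epiblast genes, 7 rose, 8 adjusted over the list alone (camera adjusted p = 2.78e-08, and adjusted p = 0.0599 with an estimated correlation), with Lef1 at 0.82 ± 0.079, Fgf15 at 0.79 ± 0.087 and the DNA methyltransferase Dnmt3a at 0.60 ± 0.085. The central pluripotency factors were not called at this time, with Pou5f1 at −0.16 ± 0.088 (adjusted p = 0.388) and Sox2 at 0.01 ± 0.080 (adjusted p = 0.971). Of 23 general pluripotency genes, 5 rose, 9 adjusted over the list alone, among them Epcam, L1td1, Lin28a and Dnmt3l at 0.34 to 0.40 (camera adjusted p = 0.00412, and adjusted p = 0.404 with an estimated correlation).

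Several targets of Nodal and BMP signalling were higher at day 1 of withdrawal. Of 16 members, 5 rose and 1 fell, 8 and 2 adjusted over the list alone, with Lefty1, Skil (0.75 ± 0.071) and Lefty2 (0.45 ± 0.14) up and Smad7 (−0.38 ± 0.083) down (camera adjusted p = 0.0256, and adjusted p = 0.229 with an estimated correlation). Of 17 hypoxia and glycolysis genes, 6 rose and 1 fell, 7 and 2 adjusted over the list alone (camera adjusted p = 0.00688, and adjusted p = 0.371 with an estimated correlation), with the glucose transporter Slc2a1 up by 0.49 and Vegfa down by 0.58. Of 22 neuroectoderm genes, 1 rose and 4 fell, the same counts adjusted over the list alone, with the neuronal tubulin Tubb3 down by 0.92 ± 0.085 and Ncam1 by 0.84 ± 0.073 (camera adjusted p = 0.0256, and adjusted p = 0.371 with an estimated correlation). Neither the Nodal and BMP list nor the neuroectoderm list was called without the 4 widest arrays. In all, 1522 clusters were called, 815 higher and 707 lower, of which 29 changed at least 2-fold. Centring each array on its median gave 588 higher and 712 lower. The count was 821 without replicate 3 of day 0, 993 and 914 without replicates 2 and 3 of day 1 withdrawal, and 2798 with the array interquartile range as a covariate, which held all 1522.

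At day 3 of withdrawal, the loss of naive genes had deepened and keratin genes of simple epithelium had risen. Slc40a1 stood 2.71 ± 0.083 and Car4, a membrane carbonic anhydrase, 2.68 ± 0.083 above day 0 (adjusted p = 1.03e-18 each). The meiotic gene Meiob rose by 3.29 ± 0.24, the coatomer subunit Copz2 by 2.19 ± 0.12 and the adhesion receptor Adgrl2 by 2.18 ± 0.095, and Otx2 reached 1.98 ± 0.11. Mras was at −2.40 ± 0.074, Khdc3 at −2.16 ± 0.12, Eras at −2.10 ± 0.12, the G1 cyclin Ccnd1 at −1.98 ± 0.080, Tubb3 at −1.94 ± 0.085, Spink1 at −1.90 ± 0.12 and Gng3 at −1.89 ± 0.11. The uncertain clusters Usp17ld, Mir363 and Mir106a were also among the 8 largest rises.

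Of the 27 naive genes, 18 fell and 1 rose at day 3, 19 and 2 adjusted over the list alone (camera adjusted p = 7.25e-11, and adjusted p = 0.0943 with an estimated correlation). Klf4 fell by 1.27 ± 0.093, the orphan receptor Nr0b1 by 1.21 ± 0.11, Zfp42 by 0.92 ± 0.097 and Esrrb by 0.66 ± 0.11, while Dppa3 rose by 0.60 ± 0.14. Pou5f1 had fallen by 0.74 ± 0.088 (adjusted p = 2.52e-07), and Sox2 stood at 0.03 ± 0.080 (adjusted p = 0.823). Fgf5, the standard marker of primed epiblast, rose by 0.87 ± 0.11. Of 19 trophectoderm genes, 10 rose and 1 fell, 10 and 2 adjusted over the list alone, with Krt7 at 1.90 ± 0.063, Krt18 at 1.64 ± 0.075, Krt8 at 1.09 ± 0.090 and the imprinted placental gene Peg10 at 1.27 ± 0.083 (camera adjusted p = 0.000679, and adjusted p = 0.103 with an estimated correlation). Keratins 7, 8 and 18 are made by many simple epithelia besides trophectoderm. Of 30 feeder fibroblast markers, 10 rose and 3 fell, likewise adjusted over the list alone, and the list was not called (camera adjusted p = 0.13).

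Lower lists at day 3 included the targets of LIF and STAT3, the signal that sustains mouse embryonic stem cells. Of 17 members, 10 fell and 4 rose, 10 and 5 adjusted over the list alone, with Myc at −1.28 ± 0.13, Gbx2 at −0.88 ± 0.12 and the receptor Lifr at −0.65 ± 0.097 (camera adjusted p = 0.00776, and adjusted p = 0.332 with an estimated correlation). Of 20 ATF4 targets, 8 fell and 3 rose, 9 and 3 adjusted over the list alone, with the serine and one-carbon enzymes Shmt2 (−0.78), Mthfd2 (−0.69) and Psat1 (−0.52) down (camera adjusted p = 0.0204, and adjusted p = 0.306 with an estimated correlation). Of 22 neuroectoderm genes, 7 fell and 2 rose, likewise adjusted over the list alone, with Neurod1 at −1.50 ± 0.11 (camera adjusted p = 0.00324, and adjusted p = 0.276 with an estimated correlation). In all, 7914 clusters were called, 4580 higher and 3334 lower, 330 of them at least 2-fold. Centring each array on its median gave 3270 higher and 4613 lower.

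At day 5 of withdrawal, most naive genes and many general pluripotency genes were lower, and keratins and extraembryonic endoderm genes were high. Krt7 had risen by 3.39 ± 0.063 (adjusted p = 6.34e-24), a 10.5-fold change, Krt18 by 2.89 ± 0.075, Krt19 by 2.50 ± 0.11 and Krt8 by 2.11 ± 0.090. The fetal growth factor Igf2 rose by 3.28 ± 0.11, Car4 by 3.41 ± 0.083, Meiob by 3.44 ± 0.24, the amyloid precursor App by 2.85 ± 0.086, Nxf7 by 2.97 ± 0.17 and the pantetheinase Vnn1 by 2.72 ± 0.11. The largest falls were Nr0b1 at −2.68 ± 0.11, Khdc3 at −2.54 ± 0.12, Gng3 at −2.53 ± 0.11, the cationic amino acid transporter Slc7a3 at −2.51 ± 0.083, Neurod1 at −2.48 ± 0.11, Ina at −2.44 ± 0.13, Ccnd1 at −2.43 ± 0.080 and Calml4 at −2.36 ± 0.14.

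Of the 27 naive genes, 22 fell and 2 rose at day 5, likewise adjusted over the list alone (camera adjusted p = 5.6e-13), and this call held with an estimated correlation (adjusted p = 0.0236). Zfp42 fell by 1.80 ± 0.097, Klf4 by 1.51 ± 0.093, Esrrb by 1.29 ± 0.11, Nanog by 1.18 ± 0.080, Prdm14 by 0.96 ± 0.074 and Klf2 by 0.27 ± 0.075, and Dppa3 stood 0.78 ± 0.14 above day 0. Of 23 general pluripotency genes, 12 fell and 5 rose, 13 and 5 adjusted over the list alone, with Pou5f1 at −1.29 ± 0.088, Dppa2 at −1.17 ± 0.082, Tet1 at −1.12 ± 0.097 and Sox2 at −0.49 ± 0.080 (camera adjusted p = 0.00132, and adjusted p = 0.277 with an estimated correlation). The formative list had split, with 5 members up and 7 down, 6 and 7 adjusted over the list alone (camera adjusted p = 0.753). Otx2 was still up by 1.30 ± 0.11, Fgf15 was down by 1.10 ± 0.087, and Fgf5 was back at 0.07 ± 0.11 (adjusted p = 0.653).

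**Figure D2:**
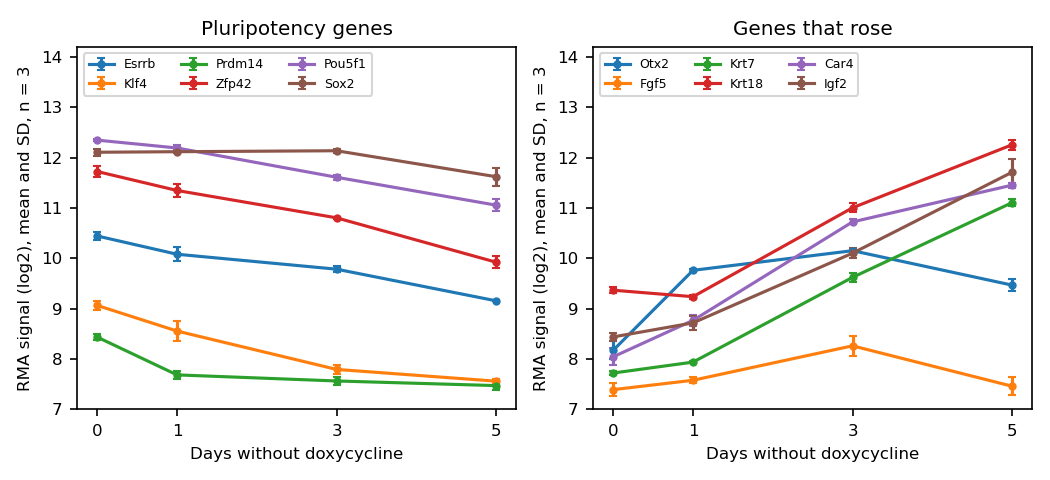
Signal (RMA, log2) against days without doxycycline for 6 pluripotency genes (left) and 6 genes that rose (right), as group means with SD (n = 3). Pou5f1 falls by 1.29 and Sox2 by 0.49 up to day 5, while Krt7 rises by 3.39 and Otx2 and Fgf5 are highest at day 3.

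Of 19 trophectoderm genes, 13 rose at day 5, 13 and 1 fell adjusted over the list alone (camera adjusted p = 6.53e-09), and the call held with an estimated correlation (adjusted p = 0.00559). Beside the keratins, Gata3 rose by 1.42 and Gata2 by 0.80, and Cdx2, the factor that sets trophectoderm apart, rose by 0.37. Elf5 was at 0.04 (adjusted p = 0.724). Of 28 extraembryonic endoderm genes, 17 rose and 1 fell, likewise adjusted over the list alone (camera adjusted p = 0.000428, and adjusted p = 0.0289 with an estimated correlation). They included the endocytic genes Dab2 (1.70 ± 0.11) and Lrp2 (1.64 ± 0.089), Srgn (1.96 ± 0.16), Sparc (1.13 ± 0.075) and the primitive endoderm factor Gata6 (0.67 ± 0.087), whereas Gata4, Sox17 and Foxa2 were at 0.12, −0.17 and −0.13 and were not called. Another cluster of Dab2 was not called, at −0.17. Of 30 feeder fibroblast markers, 11 rose and 1 fell, likewise adjusted over the list alone (camera adjusted p = 0.0554, and called with the array interquartile range as a covariate, where 12 rose and 3 fell), with Col1a2 and Mmp2 at 1.00 each and Thbs1 at 0.99.

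Signalling targets and growth genes also shifted at day 5. Of 18 ERK targets, 10 fell and 4 rose, with Myc at −2.07 ± 0.13, Etv4 at −1.54 ± 0.099 and Spry4 at −1.42 ± 0.11 (camera adjusted p = 0.000838, and adjusted p = 0.198 with an estimated correlation). Of 17 LIF and STAT3 targets, 10 fell and 3 rose (camera adjusted p = 0.000838, and adjusted p = 0.142 with an estimated correlation). Of 16 Nodal and BMP targets, 9 fell and 2 rose, with Lefty1 at −1.31 ± 0.13 and Lefty2 at −1.29 ± 0.14 down and Id2 at 1.35 ± 0.11 up (camera adjusted p = 0.0106, and adjusted p = 0.137 with an estimated correlation). The counts of these 3 lists were the same adjusted over the list alone. Of 14 Wnt targets, 5 rose and 4 fell, likewise adjusted over the list alone (camera adjusted p = 0.639), with Fzd7 up by 1.11 and Ccnd1 down. Of 26 S phase and mitosis genes, 11 fell and 6 rose, 13 and 7 adjusted over the list alone, with Ccne1 (−1.11), Rrm2 (−1.02) and Pcna (−0.72) down (camera adjusted p = 0.00459, and adjusted p = 0.422 with an estimated correlation).

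Stress and metabolic lists at day 5 included 17 p53 targets, of which 12 rose and 2 fell, 13 and 2 adjusted over the list alone, with Polk at 1.15 ± 0.087, the death receptor Tnfrsf10b at 0.93 ± 0.084 and Mdm2 at 0.81 ± 0.074 (camera adjusted p = 0.000838, and adjusted p = 0.165 with an estimated correlation). Of 20 ATF4 targets, 11 fell and 2 rose, with Shmt2, Mthfd2 and Psat1 at −1.14, −1.13 and −0.97 (camera adjusted p = 0.00106, and adjusted p = 0.107 with an estimated correlation). Of 17 hypoxia and glycolysis genes, 11 rose and 4 fell, with P4ha1 at 1.22 ± 0.087 and Ndrg1 at 0.95 ± 0.069 (camera adjusted p = 0.0129, and adjusted p = 0.277 with an estimated correlation). The counts of the last 2 lists were the same adjusted over the list alone. Of 22 Polycomb and DNA methylation genes, 11 fell and 5 rose, 11 and 6 adjusted over the list alone, with Tet1 (−1.12), Dnmt3a (−1.09), Eed (−0.96) and Tet2 (−0.96) down (camera adjusted p = 0.0106, and adjusted p = 0.277 with an estimated correlation). Another cluster of Eed was not called, at −0.027. Of 22 neuroectoderm genes, 10 fell and 3 rose, 11 and 3 adjusted over the list alone, including Neurod1, Tubb3 at −2.16 ± 0.085 and Stmn2 at −1.42 ± 0.097 (camera adjusted p = 0.000838, and adjusted p = 0.118 with an estimated correlation).

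The remaining lists were not called at day 5. Of 24 primitive streak and mesoderm genes, 4 fell and 1 rose (camera adjusted p = 0.159), with Bmp4 at −0.46 ± 0.086 and Mixl1 at −0.20 (adjusted p = 0.084). Of 15 cholesterol synthesis genes, 3 rose and 3 fell (camera adjusted p = 0.932), and of 4 measured 2-cell-like genes, 2 rose and 2 fell (camera adjusted p = 0.626). The counts of these 3 lists were the same adjusted over the list alone. Of 11 housekeeping genes, 5 fell and 2 rose, 6 and 4 adjusted over the list alone (camera adjusted p = 0.556), with Hprt at −1.16 ± 0.14. In all, 9945 clusters were called at day 5, 5558 higher and 4387 lower, 829 of them at least 2-fold. Centring each array on its median gave 4440 higher and 6119 lower.

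Between day 1 and day 3 of withdrawal, the keratins and Car4 came up and the growth regulators Ccnd1 and Myc went down. Krt18 rose by 1.77 ± 0.075, Krt7 by 1.69 ± 0.063, Car4 by 1.96 ± 0.083, Copz2 by 2.05 ± 0.12, Meiob by 2.85 ± 0.24 and Got1l1 by 1.72 ± 0.12. Ccnd1 fell by 1.58 ± 0.080, Spink1 by 1.57 ± 0.12, Myc by 1.44 ± 0.13, Hsd17b14 by 1.40 ± 0.084, Gng3 by 1.38 ± 0.11, Krt42 by 1.32 ± 0.090 and Dnmt3a by 1.02 ± 0.085. Of 27 naive genes, 12 fell and 1 rose, 13 and 4 adjusted over the list alone (camera adjusted p = 0.000107, and adjusted p = 0.282 with an estimated correlation), and of 19 trophectoderm genes, 7 rose and 1 fell, 8 and 1 adjusted over the list alone (camera adjusted p = 6.17e-05, and adjusted p = 0.0686 with an estimated correlation). In all, 5362 clusters were called, 3077 higher and 2285 lower, and 2315 and 3142 after centring each array on its median.

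Between day 3 and day 5, the Nodal antagonists Lefty1 and Lefty2 and the FGF feedback inhibitors Spry2 and Spry4 fell, while trophectoderm and endoderm genes rose further. Trh fell by 2.12 ± 0.11, Lefty1 by 1.90 ± 0.13, Slc7a3 by 1.73 ± 0.083, Lefty2 by 1.71 ± 0.14, Slc7a7 by 1.60 ± 0.086, Nr0b1 by 1.47 ± 0.11, Spry2 by 1.09 ± 0.099 and Spry4 by 1.03 ± 0.11. Fgf5 and Otx2 fell by 0.80 ± 0.11 and 0.69 ± 0.11, and Sox2 fell by 0.52 ± 0.080. Nxf7 rose by 1.74 ± 0.17, Vnn1 by 1.70 ± 0.11, Igf2 by 1.61 ± 0.11, Krt7 by 1.49 ± 0.063, Krt19 by 1.44 ± 0.11 and Myl4 by 1.38 ± 0.12. Of 19 trophectoderm genes, 13 rose, 14 adjusted over the list alone (camera adjusted p = 5.25e-18, and adjusted p = 6.15e-05 with an estimated correlation). Of 28 extraembryonic endoderm genes, 11 rose, 13 adjusted over the list alone (camera adjusted p = 3.47e-07, and adjusted p = 0.00319 with an estimated correlation). Of 16 Nodal and BMP targets, 6 fell and 2 rose, 7 and 3 adjusted over the list alone (camera adjusted p = 0.00024, and adjusted p = 0.0402 with an estimated correlation). Of 23 general pluripotency genes, 14 fell and 2 rose, 15 and 4 adjusted over the list alone, with L1td1 at −0.96 and Tdgf1 at −0.92 (camera adjusted p = 5.4e-09, and adjusted p = 0.0506 with an estimated correlation). Of 18 ERK targets, 11 fell and 3 rose, likewise adjusted over the list alone (camera adjusted p = 6.59e-07, and adjusted p = 0.0506 with an estimated correlation). In all, 2887 clusters were called, 1776 higher and 1111 lower, and 2098 and 1996 with the array interquartile range as a covariate.

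The pulsed arrays differed from their controls in 1 technical measure. The interquartile range of the arrays was lower in the pulsed group than in its control by 0.138 on day 1, 0.0955 on day 3 and 0.268 on day 5 (log2), a mean difference of −0.167 (exact permutation p = 0.0285, two-sided, 8000 assignments). Across all 30 arrays, the leading component of the deviations from the group means, with 36.3 percent of their variance, followed the deviation in interquartile range (Pearson r = 0.989, Spearman rho = 0.991, permutation p = 1e-05 each, the smallest that 100000 resamples can give). The Pearson r was 0.985 without the 2 arrays whose interquartile range deviated most from their group mean. Across clusters, which are not independent replicates, the pulse effects correlated with this component at −0.44, −0.46 and −0.72 on days 1, 3 and 5, and the withdrawal effects at −0.01, 0.16 and 0.21. The widest arrays were control replicates 2 and 3 of day 5 (2.95 and 2.93), control replicate 2 of day 3 (2.84) and control replicate 3 of day 1 (2.77).

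**Figure D3:**
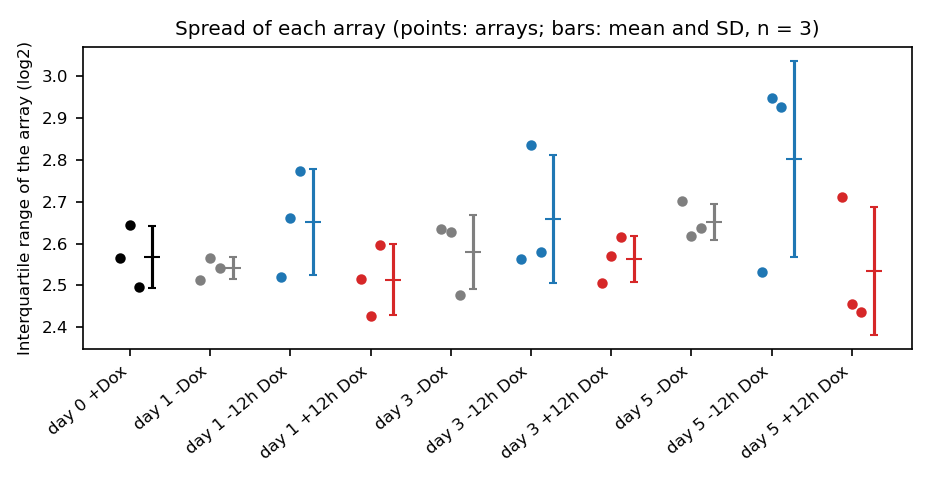
Interquartile range of each array (log2) on the vertical axis for the 10 groups on the horizontal axis. Points are arrays and bars are group means with SD (n = 3). The time-matched controls without doxycycline reach 2.95 on day 5, and the pulsed arrays of that day lie at 2.71 or below.

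On day 1, relative to the time-matched control, several of the naive genes that had just fallen were higher after the 12 h pulse, and formative genes that had just risen were lower. Mras rose by 1.05 ± 0.074 (adjusted p = 2.09e-09), Calcoco2 by 0.78 ± 0.17, Rab27a by 0.71 ± 0.10, Prdm14 by 0.70 ± 0.074, Tubb3 by 0.68 ± 0.085, Gng3 by 0.65 ± 0.11 and Klf4 by 0.39 ± 0.093 above the time-matched control. Another cluster of Mras was not called, at 0.32. Apela, a peptide hormone gene of the early embryo, fell by 0.96 ± 0.12, Greb1l by 0.86 ± 0.13, Car4 by 0.77 ± 0.083, the Wnt receptor Fzd7 by 0.63 ± 0.085, Krt7 by 0.55 ± 0.063, Fgfr2 by 0.53 ± 0.067 and Otx2 by 0.51 ± 0.11. Car4 and Krt7 had risen further in the control. Car4 stood at 8.76 in the day 1 withdrawal, 9.80 in the control and 9.04 in the pulsed arrays, and Krt7 at 7.93, 8.57 and 8.02. Mras and Otx2 did move back, from 7.69 and 9.76 in the day 1 withdrawal to 8.45 and 9.46 in the pulsed arrays. The microRNA and small RNA clusters Mir15b, Mir106a, Snora44, Mir300 and Mir382 were also among the 8 largest falls, and Olfr237 among the 8 largest rises. Esrrb, Zfp42, Pou5f1 and Sox2 were at −0.12, 0.27, 0.06 and −0.07 and were not called.

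Of 17 p53 targets, 8 fell with the day 1 pulse, 11 adjusted over the list alone (camera adjusted p = 9.09e-11), and the call held with an estimated correlation (adjusted p = 0.0295). Zmat3 fell by 0.63 ± 0.13, Phlda3 by 0.60 ± 0.13, Ei24 by 0.58 ± 0.078 and Trp53inp1 by 0.39 ± 0.065. The median of the list was −0.28, and −0.22 with the array interquartile range as a covariate. Of 19 formative genes, 5 fell, 11 adjusted over the list alone, including Igfbp2 (−0.46 ± 0.074) and Nodal (−0.35 ± 0.087) (camera adjusted p = 1.09e-06, and adjusted p = 0.117 with an estimated correlation). Of 27 naive genes, 6, Nanog itself among them, rose and 1 fell, 8 and 4 adjusted over the list alone (camera adjusted p = 0.0209, and adjusted p = 0.508 with an estimated correlation), the fall being Tfcp2l1 (−0.46 ± 0.079). Of 18 ERK targets, 4 fell and 1 rose, 5 and 3 adjusted over the list alone, with Spry4 (−0.55 ± 0.11) and Dusp4 (−0.52 ± 0.11) down (camera adjusted p = 0.0384, and adjusted p = 0.508 with an estimated correlation). This list, the trophectoderm list (3 of 19 fell, 4 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0371, and adjusted p = 0.424 with an estimated correlation) and the neuroectoderm list (2 of 22 rose, 3 adjusted over the list alone, camera adjusted p = 0.0269, and adjusted p = 0.424 with an estimated correlation) were not called with the array interquartile range as a covariate. Of 20 ATF4 targets, 3 rose, 6 rose and 2 fell adjusted over the list alone, among them Trib3 at 0.33 (camera adjusted p = 0.00172, and adjusted p = 0.117 with an estimated correlation).

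In all, the day 1 pulse called 877 clusters, 128 higher and 749 lower. Of the 815 clusters that had risen in the withdrawal, 199 fell with the pulse, where independent lists would share 26.1, and of the 707 that had fallen, 57 rose, where independent lists would share 3.87. The split of calls was 308 higher and 651 lower after quantile normalization and 406 and 678 with the interquartile range as a covariate, which shared 724 of the calls. The count was 319 without control replicate 2, 372 and 288 without pulsed replicates 1 and 2, and 74 when the compared groups alone were fitted.

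On day 3, 9 clusters were called with the pulse, Nanog higher and 8 lower. The falls were the lysophosphatidic acid receptor Lpar4 (−0.66 ± 0.12), Wnt8a (−0.57 ± 0.11), Ap3b2 (−0.47 ± 0.072), Slc40a1 (−0.46 ± 0.083), Fgfr2 (−0.37 ± 0.067), the amino acid transporter Slc38a2 (−0.36 ± 0.060), the gap junction gene Gja1 (−0.34 ± 0.066) and Flvcr1, named here after its values were seen. Of these, 7 had risen in the day 3 withdrawal, where independent lists would share 1.57. Prdm14 was at 0.36 ± 0.074 (adjusted p = 0.0705), Zfp42 at 0.36 ± 0.097 (adjusted p = 0.148), Klf4 at 0.31 ± 0.093 (adjusted p = 0.171), and Otx2 at −0.24 ± 0.11 (adjusted p = 0.299). Of 27 naive genes, 1 rose, which was Nanog itself, and 7 rose adjusted over the list alone (camera adjusted p = 5.89e-08, and adjusted p = 0.267 with an estimated correlation). Of 19 formative genes, 8 fell adjusted over the list alone (camera adjusted p = 0.00106, and adjusted p = 0.38 with an estimated correlation), as did 4 of 19 trophectoderm genes (camera adjusted p = 0.00785, and adjusted p = 0.36 with an estimated correlation) and 3 of 17 p53 targets (camera adjusted p = 0.00292, and adjusted p = 0.38 with an estimated correlation). The formative list was not called without the 4 widest arrays. Without any single array the count was 1 to 4, namely 3, 1 and 2 without control replicates 1 to 3 and 1, 4 and 1 without pulsed replicates 1 to 3. It was 67 with the array interquartile range as a covariate, 26 higher and 41 lower, and 26 after quantile normalization, 14 higher and 12 lower.

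On day 5, the pulse lowered the glucose-responsive arrestin genes Txnip and Arrdc4, the peptide hormone gene Apela and the homeobox gene Obox6. Txnip fell by 0.82 ± 0.074 (adjusted p = 5.93e-07), Apela by 0.96 ± 0.12, Obox6 by 1.18 ± 0.13, Meiob by 1.76 ± 0.24, Gstm3 by 0.87 ± 0.13, Epp13 by 0.86 ± 0.094, Cntd1 by 0.85 ± 0.10, Dppa3 by 0.76 ± 0.14, Lefty1 by 0.67 ± 0.13 and Otx2 by 0.65 ± 0.11. Another cluster of Obox6 was not called, at 0.047. Tubb3 rose by 0.50 ± 0.085, Myc by 0.44 ± 0.13, Ccnd1 by 0.43 ± 0.080, Krt8 by 0.41 ± 0.090, Spry4 by 0.37 ± 0.11 and Prdm14 by 0.28 ± 0.074. All of these genes remained called with the array interquartile range as a covariate. Leaving out the 4 widest arrays leaves 1 control array on this day (replicate 1, with the lowest score on the component of array spread), so that the control's variance comes from the other groups. In that fit Txnip, Apela, Obox6, Epp13, Cntd1 and Spry4 remained called, and Meiob, Gstm3, Dppa3, Lefty1, Otx2, Tubb3, Myc, Ccnd1, Krt8 and Prdm14 did not. Arrdc4, named after its values were seen and not refitted with these alternatives, fell by 0.77. Zfp42, Esrrb, Klf4 and Pou5f1 were at 0.22, 0.17, −0.02 and −0.17 and were not called.

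Many other day 5 calls moved with the array spread. Apart from Nanog, the 8 largest rises were Igkv5-43, Hamp, Vmn1r86, Olfr1028, Olfr149, Vmn1r48 and Lce1i, at 0.73 to 1.01, and with the interquartile range as a covariate only Olfr149 among these was called. Of 1209 clusters of olfactory and vomeronasal receptors, 175 rose and 2 fell, with a median of 0.23, and 10 were called with a median of 0.035 once the interquartile range was a covariate. Of 23 general pluripotency genes, 3 fell, likewise adjusted over the list alone, with Dppa4 at −0.36 ± 0.074 (camera adjusted p = 0.00974, and adjusted p = 0.605 with an estimated correlation), and of 26 S phase and mitosis genes, 7 fell and 2 rose, 9 and 3 adjusted over the list alone, with Cenpe at −0.35 ± 0.076 (camera adjusted p = 0.0455, and adjusted p = 0.605 with an estimated correlation). Neither list was called with that covariate. The trophectoderm list (3 rose) and the ERK list (2 rose) were called higher with it and not without it, as was cholesterol synthesis without a called member. Of 27 naive genes, 2 rose and 6 fell, 3 and 7 adjusted over the list alone (camera adjusted p = 0.353). In all, 2860 clusters were called, 1200 higher and 1660 lower. With the covariate 537 were called, 293 higher and 244 lower, of which 331 were among the 2860, and without the 4 widest arrays 55. None was called when the compared groups alone were fitted. The count was 8617, 520 and 681 without control replicates 1, 2 and 3, and 5297, 568 and 695 without pulsed replicates 1, 2 and 3.

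Averaged over the 3 days, the pulse raised Nanog by 0.79 ± 0.046 (adjusted p = 2.54e-11) relative to the time-matched controls. Among naive genes, Prdm14 was higher by 0.44 ± 0.043 (adjusted p = 4.47e-07), Mras by 0.40 ± 0.043, Calcoco2 by 0.31 ± 0.099, Zfp42 by 0.28 ± 0.056 and Klf4 by 0.23 ± 0.054. Not all of this was a move back. Zfp42 stood at 11.35 in withdrawal and 11.41 in pulsed arrays on day 1, 10.80 and 10.86 on day 3, and 9.92 and 10.42 on day 5. Prdm14 moved from 7.68 to 8.31 on day 1. Rab27a rose by 0.41 ± 0.060 and Naaa, a lysosomal amidase, by 0.37 ± 0.048. Meiob fell by 0.86 ± 0.14, Apela by 0.74 ± 0.069, Greb1l by 0.67 ± 0.072, Prr5l by 0.56 ± 0.077, Serinc5 and Epp13 by 0.55 each, Lefty1 by 0.47 ± 0.072, Otx2 by 0.47 ± 0.063, Fzd7 by 0.42 ± 0.049 and Fgfr2 by 0.34 ± 0.039. The naive genes Esrrb, Tbx3 and Klf2 were at 0.11, 0.00 and −0.02 and were not called, nor were Pou5f1 (0.01) and Sox2 (−0.09). Dppa3 fell by 0.26 ± 0.083. Of 27 naive genes, 7, Nanog itself among them, rose and 6 fell, 11 and 7 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0623). With the interquartile range as a covariate, 11 rose and 1 fell, and it was called. Of 17 p53 targets, 9 fell, 12 adjusted over the list alone (camera adjusted p = 3.75e-06, and adjusted p = 0.235 with an estimated correlation), and 2 fell with the interquartile range as a covariate. Of 19 formative genes, 10 fell and 1 rose, likewise adjusted over the list alone (camera adjusted p = 0.00146, and adjusted p = 0.554 with an estimated correlation), and 2 fell and 2 rose with the covariate. In all, 4860 clusters were called, 1591 higher and 3269 lower, and 841 with the covariate, of which 593 were among them. Leaving out control replicates 1, 2 or 3 of day 5 gave 9253, 2568 or 3122, control replicate 2 of day 3 gave 2539, pulsed replicate 2 of day 1 gave 3088, and pulsed replicates 2 or 3 of day 5 gave 3092 or 2949.

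The reversal slope was 0.347 on day 1 (1522 clusters, exact permutation p = 0.1), 0.196 on day 3 (7914 clusters, exact permutation p = 0.1) and 0.102 on day 5 (9945 clusters, exact permutation p = 0.2). It does not tell withdrawal change that was undone from further change that was prevented during the 12 h. Each pulsed array alone gave 0.28 to 0.381 on day 1, 0.154 to 0.241 on day 3 and 0.0697 to 0.138 on day 5. The mean of the 3 slopes was 0.215 (exact permutation p = 5e-04, two-sided, 8000 assignments). That test does not tell a response to the pulse from the difference in array spread between pulsed and control arrays. Opposite correlations of the pulse and withdrawal effects with the component of array spread, as on days 3 and 5, can add to the slope. The mean slope was 0.290 (exact permutation p = 5e-04) over genes that had risen in the withdrawal and 0.106 (exact permutation p = 0.0848) over genes that had fallen, and the difference was not tested. On day 5 alone these slopes were 0.186 (exact permutation p = 0.2) and −0.037 (exact permutation p = 0.6), so no reversal was seen there for genes that had fallen. With the interquartile range as a covariate, both kinds were shared beyond independent lists on day 1, 256 against 48.0 and 134 against 19.8, and on day 5, 151 against 66.1 and 157 against 62.4. Without the covariate, day 5 gave 952 against 395 for genes that had risen, and 168 against 225, fewer than independent lists, for genes that had fallen. Genes that rose in both were fewer still, 67 against 285. Without the 4 widest arrays the day 5 slope was 0.012, against the single control array left (replicate 1), whose score on the component of array spread was the lowest of the series (−25.5). With the array interquartile range as a covariate it was 0.0425, and it was 0.149 and 0.0654 without control replicates 1 and 2 of that day. The decline over the days was not tested.

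**Figure D4:**
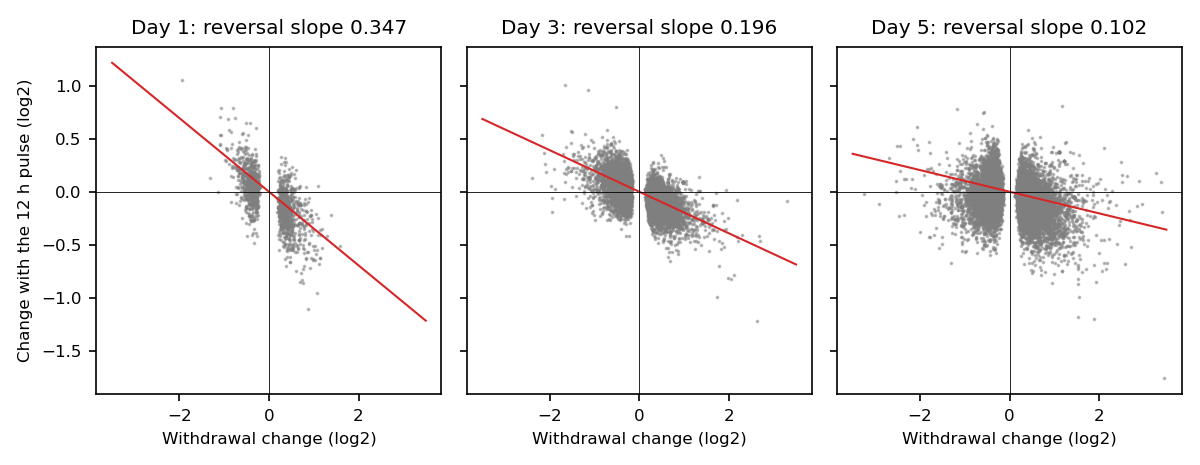
Change with the 12 h pulse (log2, vertical axis) against the withdrawal change of the same day (log2, horizontal axis). Points are the clusters called in that day's withdrawal, and the line is the reversal slope through 0, at 0.347 for day 1, 0.196 for day 3 and 0.102 for day 5.

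Tests of the difference between the pulses of 2 days called few genes, and chance was not excluded for their numbers, since 9, 17 and 12 of 100 splits of the arrays, the real one included, gave as many. Mras rose with the pulse on day 1 but stood 0.92 ± 0.11 lower in its response on day 3 (adjusted p = 6.67e-05) and 1.01 ± 0.11 lower on day 5 (adjusted p = 9.03e-06), that is at differences of −0.919 and −1.014. Another cluster of Mras was called in neither comparison, at −0.152 between day 3 and day 1 and 0.11 between day 5 and day 1. Tubb3 responded less on day 3 than on day 1 (−0.74 ± 0.12, adjusted p = 0.0207), and Mras and Tubb3 were the 2 clusters called in that comparison. Without the 4 widest arrays Mras remained called and Tubb3 did not (adjusted p = 0.0567). Between day 5 and day 1, 26 clusters were called, 14 higher and 12 lower, with the ERK feedback inhibitor Spry4 at 0.92 ± 0.15 and Zfp979, Vstm5 and the peptidase Mme at −0.95 ± 0.19, −0.76 ± 0.15 and −0.74 ± 0.13. Between day 5 and day 3, 219 were called, 83 higher and 136 lower, with Meiob at −1.67 ± 0.34, Obox6 at −1.21 ± 0.18, Gstm3 at −1.001 ± 0.18, Dppa3 at −0.995 ± 0.20 and Igkv5-43 at 1.15 ± 0.28. The split of the latter was 26 higher and 84 lower after median centring, 416 and 395 after quantile normalization, 553 and 280 with the array interquartile range as a covariate, and 38 and 3 without the 4 widest arrays. The last 2 alternatives gave 240 and 82, and 46 and 7, between day 5 and day 1. The 26 calls became 8, 8 and 418 without control replicates 1 to 3 of day 1, 5, 7 and 7 without its pulsed replicates 1 to 3, 349 and 5 without control replicates 1 and 3 of day 5, and 3 and 4 without its pulsed replicates 2 and 3. The 219 became 27 and 45 without control replicates 1 and 3 of day 3, 69 and 20 without its pulsed replicates 2 and 3, 881, 123 and 81 without control replicates 1 to 3 of day 5, and 346, 26 and 50 without its pulsed replicates 1 to 3.

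Over the 12 further hours without doxycycline on day 1, keratins and p53 targets rose. Krt7 rose by 0.63 ± 0.063 (adjusted p = 1.53e-06), Krt18 by 0.60 ± 0.075, Cldn6, a tight junction gene, by 0.64 ± 0.076, Krt19 by 0.50 ± 0.11 and Fgf5 by 0.49 ± 0.11, while Ccnd1 fell by 0.58 ± 0.080, Id3 by 0.58 ± 0.14, Tubb3 by 0.51 ± 0.085, Klf4 by 0.38 ± 0.093 and Mras by 0.29 ± 0.074. Nanog was at 0.07 ± 0.080 (adjusted p = 0.712). Of 17 p53 targets, 8 rose, 9 adjusted over the list alone, with Zmat3 at 0.49 and Trp53inp1 at 0.35 (camera adjusted p = 0.000477, and adjusted p = 0.24 with an estimated correlation), and of 19 trophectoderm genes, 5 rose, likewise adjusted over the list alone (camera adjusted p = 0.00377, and adjusted p = 0.235 with an estimated correlation). In all, 1462 clusters were called, 1174 higher and 288 lower. The split was 569 and 293 after median centring and 1097 and 646 after quantile normalization, and the count was 490 and 755 without replicates 1 and 3 of day 1 withdrawal and 549 without control replicate 2.

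Over the 12 further hours on days 3 and 5, genes of the hypoxia response and glycolysis rose together. On day 3, 12 of 17 members rose, likewise adjusted over the list alone (camera adjusted p = 1.24e-27, and adjusted p = 0.000104 with an estimated correlation), with Ndrg1 at 0.93 ± 0.069, the oxygen sensor Egln3 at 0.84 ± 0.11, Higd1a at 0.76 ± 0.19 and the mitophagy receptor Bnip3 at 0.65 ± 0.075. On day 5, 7 rose, 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.47e-11, and adjusted p = 0.0117 with an estimated correlation), with Ndrg1 at 1.01 ± 0.069 and Bnip3 at 0.54 ± 0.075, and 2 rose without the 4 widest arrays. Trophectoderm genes rose on both days, 6 of 19 on day 3, 7 adjusted over the list alone (camera adjusted p = 8.98e-06, and adjusted p = 0.0228 with an estimated correlation), and 8 on day 5, 12 adjusted over the list alone (camera adjusted p = 4.35e-11, and adjusted p = 0.00138 with an estimated correlation). Without the 4 widest arrays, 4 rose on day 3 and 1 on day 5, where that fit, as for the hypoxia list, has a single control array. Krt19 rose by 0.88 ± 0.11 and Krt8 by 0.70 ± 0.090 on day 3, and the placental gene Plac1 by 1.72 ± 0.16, Ascl2 by 0.63 ± 0.098 and Tfap2c by 0.48 ± 0.065 on day 5. Some keratins were also higher in the pulsed arm. Krt8 stood at 12.19 in withdrawal, 12.56 in control and 12.97 in pulsed arrays on day 5. Krt7 stood at 9.62, 9.88 and 9.60 on day 3. The list was not tested between pulsed and withdrawal arrays.

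Other groups changed over the further 12 h of day 5. Of 26 S phase and mitosis genes, 7 rose, 14 adjusted over the list alone, with Rrm2 at 0.49 ± 0.085 (camera adjusted p = 2.33e-10, and adjusted p = 0.151 with an estimated correlation), and no member was called without the 4 widest arrays, though the list was, in a fit with a single control array. Of 30 feeder fibroblast markers, 5 fell and 1 rose, 6 and 1 adjusted over the list alone, with the contractile genes Acta2 (−0.76 ± 0.10) and Tagln (−0.65 ± 0.14) down (camera adjusted p = 0.000702, and adjusted p = 0.126 with an estimated correlation), and in that fit 3 fell and the list was not called. Myc rose by 0.97 ± 0.13, the transferrin receptor Tfrc by 0.69 ± 0.079 and Pou5f1 by 0.39 ± 0.088. On day 3, Ier3 rose by 1.09 ± 0.14, Prdm14 rose by 0.31 ± 0.074, and Nanog fell by 0.34 ± 0.080 (adjusted p = 0.0223). The 2 days gave 396 calls, 302 higher and 94 lower, and 773 calls, 543 higher and 230 lower. The splits were 366 and 268 on day 3 and 506 and 421 on day 5 after quantile normalization, and 482 and 358, and 551 and 725, with the array interquartile range as a covariate. Across clusters, the changes over the further 12 h correlated with the component of array spread at 0.43, 0.37 and 0.40 on days 1, 3 and 5. The day 3 count was 207 and 188 without withdrawal replicates 2 and 3 and 212 and 151 without control replicates 1 and 2. The day 5 count was 262 and 267 without withdrawal replicates 2 and 3 and 3134 and 140 without control replicates 1 and 3.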

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

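The tests of clusters with no gene symbol, those with the array spread alternatives and those that weigh the 3 patterns at the end of this part were chosen after the data were seen, and of the latter only the overlap test of the day 5 falls and the array spread test of the hypoxia genes were written before their own results.

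Tests of the difference between the pulses of 2 days called the genes and lists that follow, though chance was not excluded for the numbers of genes. Between day 3 and day 1, 2 clusters were called, Tubb3 (−0.736) and Mras (−0.919), and 3 lists were, with median differences of 0.189 for p53 targets, −0.141 for ATF4 targets and −0.133 for cholesterol synthesis, the last not called without the 4 widest arrays, a fit that leaves 1 control array on day 5. Between day 5 and day 1, 26 clusters were called, among them Spry4 (0.917), Mme (−0.744), Vstm5 (−0.757), Zfp979 (−0.948) and Mras (−1.014). The lists called there had medians of −0.143 for naive pluripotency, 0.154 for the formative epiblast, 0.233 for trophectoderm, −0.064 for S phase and mitosis, 0.180 for p53 targets and −0.187 for ATF4 targets. Of these, S phase and mitosis was called neither with the interquartile range as a covariate (median −0.022) nor without the 4 widest arrays, and naive pluripotency and ATF4 targets were not called without those arrays. Between day 5 and day 3, 219 clusters were called, among them Igkv5-43 (1.154), Dppa3 (−0.995), Gstm3 (−1.001), Obox6 (−1.212) and Meiob (−1.668). The lists there had medians of −0.139 for naive pluripotency, −0.121 for general pluripotency and 0.252 for trophectoderm. General pluripotency was called neither with the covariate (median −0.054) nor without the 4 widest arrays. None of these list differences was called with an estimated correlation, where the smallest adjusted p was 0.11, for trophectoderm between day 5 and day 1.

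A signal was also present in clusters outside the comparisons. Of the 5430 clusters with no gene symbol, 1539 were called in a separate test of day 5 of withdrawal against day 0, 703 higher and 836 lower, and no explanation was tested.

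Other splits of the same arrays were counted for each number of calls. A comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. Each other split mixes arrays of both groups, so a true difference between the groups widens the spread within the mixed ones and hides calls. Low counts in the other splits are therefore not evidence by themselves. The real split was the 1 with the most calls for withdrawal at day 1 (1522, highest other 20), day 3 (7914, highest other 0) and day 5 (9945, highest other 0), for the steps (5362 and 2887, highest other 0 each), for the pulse on day 1 (877, highest other 0) and day 3 (9, highest other 0), and for the further 12 h on days 1, 3 and 5 (1462, 396 and 773, highest others 4, 0 and 37). For the pulse on day 5, 2 of the 10 splits had at least the 2860 calls of the real one, and the highest other had 9465. That split set control replicates 2 and 3 and pulsed replicate 1, with interquartile ranges of 2.95, 2.93 and 2.71, against control replicate 1 and pulsed replicates 2 and 3, with 2.53, 2.46 and 2.44, which points to the array spread as a structure of these samples. For the pulse average, 2 of 100 splits, the real one included, reached the real 4860 calls, and the highest other had 10143. That share lies under 0.05. It does not exclude a chance placing of wide arrays among the controls, which the count does not tell apart from the pulse. With the interquartile range as a covariate, 841 clusters were called. For the differences between pulses, 9, 17 and 12 of 100 splits reached the real 2, 26 and 219 calls, with highest others of 259, 10724 and 8816, so chance was not excluded for these 3 counts.

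The 2860 calls of the day 5 pulse were weighed between array spread and a response to the pulse. With the interquartile range as a covariate 537 calls were made, of which 331 were among the 2860, which is consistent with a difference in array spread as the source of most of the 2860. Among the calls without the covariate, 168 clusters that had fallen in the withdrawal rose with the pulse, fewer than the 225 of independent lists. Clusters that had risen in the withdrawal were also scarce among these rises, 67 against 285. Since both directions fell short of independent lists, this count cannot decide whether the rises as first called were an undoing of the withdrawal. Of the 1660 falls as first called, 952 had risen in the withdrawal against 395 of independent lists. An undoing would give this, though that count does not set the array spread apart. Among the falls called with the covariate, 151 had risen in the withdrawal against 66.1 of independent lists, which a response that undoes the withdrawal would give, and among the rises called with it, counted after the fact, 157 had fallen against 62.4. Clusters that moved the same way in both were fewer than in independent lists, 58 against 79.4 for rises and 35 against 52.0 for falls. The trophectoderm list, higher in the withdrawal, was also called higher in the pulse with the covariate (median 0.128, 3 of 19 members called). An undoing would not give this for those genes, so the source of the 537 calls as a whole stays open.

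The hypoxia and glycolysis genes rose in the control over the further 12 h of days 3 and 5, by list means of 0.434 ± 0.040 and 0.293 ± 0.040 (log2, SE). Pulsed and control arrays differed in this list by −0.038 ± 0.040 and −0.019 ± 0.040, which argues against the missing doxycycline as the source. The pulsed arrays also stood above the withdrawal arrays, by 0.397 and 0.274, as something shared by both arms over the 12 further hours of culture would give. On day 1 the same 12 h gave 0.035 ± 0.040 in the control and 0.063 ± 0.040 in the pulsed arrays, so 12 further hours alone do not account for the rise, and its source stays open. With the interquartile range as a covariate the rises were 0.409 and 0.245, which argues against array spread as their source.

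The p53 targets fell with the pulse on day 1, by a list mean of −0.283 ± 0.043, and the same control arrays stood 0.187 above the day 1 withdrawal arrays. With the interquartile range as a covariate the mean was −0.231, which argues against array spread as the whole source. Over days 3 and 5 the mean difference was −0.113 (exact permutation p = 0.025), and −0.045 with the covariate (exact permutation p = 0.07), made up of −0.095 ± 0.023 on day 3 and 0.004 ± 0.023 on day 5. Without the covariate, the difference between the pulsed and the withdrawal arrays was −0.096 ± 0.043 on day 1, −0.116 ± 0.043 on day 3 and −0.172 ± 0.043 on day 5. This difference counts the further hours of culture as well as the pulse. With the covariate, control minus withdrawal arrays was 0.145 ± 0.023 on day 1, −0.015 ± 0.023 on day 3 and −0.132 ± 0.023 on day 5. The day 1 difference between pulsed and withdrawal arrays therefore cannot decide between the pulse and control arrays that stand apart. Since the test of the other days missed its threshold with the covariate, a response to the pulse and control arrays that stand apart were not told apart as the main source.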

How the results depend on the processing

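The array spread covariate, the fit without the 4 widest arrays and the scaling alternatives of the gene lists were chosen after the data were seen. The cause of a moved value was not tested, except that the 2-fold minimum asks for a larger change by design. The fit of the compared groups alone leaves fewer arrays for the variance, and the fit without the 4 widest arrays leaves 1 control array on day 5.

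The withdrawal counts of days 3 and 5 and both steps stayed within 1.5 times as single arrays were left out, and the day 1 count did not. Day 1 had 1522 calls, 3859 with array weights, 2798 with the array interquartile range as a covariate, 29 at the 2-fold minimum, 821 without replicate 3 of day 0, and 1208, 993 and 914 without replicates 1, 2 and 3 of day 1. Days 3 and 5 had 7914 and 9945, and moved only at the 2-fold minimum, to 330 and 829. The steps had 5362 and 2887, with 8789 and 4998 under array weights and 109 and 60 at the 2-fold minimum. The slope of day 1 was 0.409 among clusters changed at least 2-fold, against 0.347.

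For the pulse on day 1, the 877 calls became 4573 with array weights, 1405 without the 4 widest arrays, 74 with the compared groups alone and 3 at the 2-fold minimum. Leaving out control replicates 2 and 3 gave 319 and 906, and pulsed replicates 1 and 2 gave 372 and 288.

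For day 3, the 9 calls became 43 with trend and robust settings, 2 after median centring, 26 after quantile normalization, 60 without dim clusters, 1865 with array weights, 67 with the covariate and 2 without the 4 widest arrays. The compared groups alone gave 1, and the 2-fold minimum gave 0. Leaving out control replicates 1, 2 and 3 gave 3, 1 and 2, and pulsed replicates 1, 2 and 3 gave 1, 4 and 1.

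For day 5, the 2860 calls became 11154 with array weights, 537 with the covariate, 55 without the 4 widest arrays, 0 with the compared groups alone and 5 at the 2-fold minimum. Leaving out control replicates 1, 2 and 3 gave 8617, 520 and 681, and pulsed replicates 1, 2 and 3 gave 5297, 568 and 695. The day 5 slope of 0.102 became 0.0425 with the covariate, 0.012 without the 4 widest arrays, and 0.149 and 0.0654 without control replicates 1 and 2.

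The pulse average had 4860 calls, 2758 after quantile normalization, 11125 with array weights, 841 with the covariate, 496 without the 4 widest arrays, 2866 with the compared groups alone and 0 at the 2-fold minimum. Leaving out pulsed replicate 2 of day 1 gave 3088, control replicate 2 of day 3 gave 2539, control replicates 1, 2 and 3 of day 5 gave 9253, 2568 and 3122, and pulsed replicates 2 and 3 of day 5 gave 3092 and 2949.

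The difference between the pulses of day 3 and day 1 had 2 calls, 12 with trend and robust settings, 21 after quantile normalization, 10 without dim clusters, 1142 with array weights, 62 with the covariate, 1 with the compared groups alone and 0 at the 2-fold minimum. It had 1 without control replicate 1 of day 1, pulsed replicates 2 or 3 of day 1, control replicate 1 of day 3 or pulsed replicate 3 of day 3.

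Between day 5 and day 1, the 26 calls became 10 with the replicate block, 71 with trend and robust settings, 9 after median centring, 216 after quantile normalization, 74 without dim clusters, 41 with clusters lacking a symbol included, 4827 with array weights, 322 with the covariate, 53 without the 4 widest arrays, 1 with the compared groups alone and 1 at the 2-fold minimum. Leaving out control replicates 1, 2 and 3 of day 1 gave 8, 8 and 418, pulsed replicates 1, 2 and 3 of day 1 gave 5, 7 and 7, control replicates 1 and 3 of day 5 gave 349 and 5, and pulsed replicates 2 and 3 of day 5 gave 3 and 4.

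Between day 5 and day 3, the 219 calls became 614 with trend and robust settings, 110 after median centring, 811 after quantile normalization, 534 without dim clusters, 7199 with array weights, 833 with the covariate, 41 without the 4 widest arrays, 0 with the compared groups alone and 7 at the 2-fold minimum. Leaving out control replicates 1 and 3 of day 3 gave 27 and 45, pulsed replicates 2 and 3 of day 3 gave 69 and 20, control replicates 1, 2 and 3 of day 5 gave 881, 123 and 81, and pulsed replicates 1, 2 and 3 of day 5 gave 346, 26 and 50.

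Over the further 12 h, the 1462 calls of day 1 became 862 after median centring, 4302 with array weights, 122 with the compared groups alone, 5 at the 2-fold minimum, 490 and 755 without withdrawal replicates 1 and 3, and 1395 and 549 without control replicates 1 and 2. The 396 of day 3 became 634 after quantile normalization, 1228 with array weights, 840 with the covariate, 55 with the compared groups alone, 5 at the 2-fold minimum, 280, 207 and 188 without withdrawal replicates 1, 2 and 3, and 212 and 151 without control replicates 1 and 2. The 773 of day 5 became 4628 with array weights, 1276 with the covariate, 110 without the 4 widest arrays, 19 with the compared groups alone, 3 at the 2-fold minimum, 262 and 267 without withdrawal replicates 2 and 3, and 3134 and 140 without control replicates 1 and 3.

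Of 300 list tests 99 were called, 11 with an estimated correlation and 210 in the mixed test of fry. Other clusters of 5 named genes reversed the sign. They were Dab2 in the withdrawal (−0.097 at day 3 and −0.17 at day 5), in the step to day 3 (−0.03) and in the pulse average (0.209), Eed at day 3 (0.078) and in the step to day 3 (0.086), Higd1a in that step (0.018), Obox6 in the day 5 pulse (0.047) and Mras in the difference between day 5 and day 1 (0.106), of which only Dab2 in the pulse average was called. Replicate numbers did not pair the arrays, with 5 of 18 pairs above 0.1, a mean correlation of −0.015 for the same number and 0.007 for different numbers, and 8 of 30 arrays closest to their own number.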

Other observations

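The values in this part were chosen after the data were seen, and no explanation of them was tested.

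Hprt, a purine salvage enzyme often used as a constant reference, fell through the withdrawal by 0.46 ± 0.14 at day 1, 0.87 ± 0.14 at day 3 and 1.16 ± 0.14 at day 5 (adjusted p = 0.0381, 1.29e-05 and 7.26e-08). In Ainv15 cells the doxycycline-driven gene is placed next to Hprt, and whether the Nanog of NgR lies there was not examined. With the pulse Hprt stood at 0.12 on day 1, 0.40 on day 3 and 0.00 on day 5, and was not called. Among the other reference genes, Actb stood at 0.10 at day 5 (adjusted p = 0.0935), Pgk1 rose by 0.31 ± 0.056 and Tbp fell by 0.23 ± 0.073.

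Txnip and Arrdc4 are arrestin-like genes that respond to glucose. They rose by 1.37 and 0.72 at day 3 of withdrawal and by 1.53 and 0.99 at day 5. Over the further 12 h of day 3 without doxycycline they fell by 0.64 and 0.53, and in that day's pulse they stood at 0.00 and −0.22 and were not called. On day 1 Txnip stood at 10.94 ± 0.071 (SD) in the pulsed arrays and 11.38 ± 0.121 in their control. Greb1l, a gene linked to retinoic acid signalling, rose by 0.77, 1.86 and 2.57 at days 1, 3 and 5 of withdrawal and fell by 0.86 and 0.68 with the pulse on days 1 and 5. Apela rose by 1.07 and 0.97 at days 1 and 3 of withdrawal, and fell by 0.96 with the pulse on day 1 and by 0.96 on day 5.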
